A study of Arabidopsis thaliana with 6 samples.

How the data were processed

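Gene expression was measured with Affymetrix ATH1 arrays, which carry short oligonucleotides for Arabidopsis thaliana transcripts, in whole 10-day-old seedlings of the wild type Col-0 and of the mutant rns2-2. Each genotype had 3 arrays, which the labels describe as independent biological samples, and each array received biotin-labelled RNA amplified from 250 ng of total RNA. The amplification started from the 3' ends of transcripts, per the labels' protocols.

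The deposited values were log2 signals, 1 per probe set and array, and the scale was read from the values themselves, which ran from 3.21 to 14.49. The authors made them in Affymetrix Expression Console, per the submitters' processing notes. The algorithm, its version and any normalization between arrays were not given in the sources used here. The array medians ran from 6.51 to 6.66, so the arrays had similar but not identical distributions. No detection calls were used, so a low value cannot be separated from background here, and the number of arrays limits the precision.

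The value table held 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests, which left 22746. Gene names came from a platform annotation table, updated through Entrez gene identifiers in a RefSeq gene table (TAIR10.1) that served only for names and for neighbouring loci. It paired 13436 probe sets with 1 locus each, for 13286 loci, and 503 with several loci, which were tested but not named. A further 77 had an entry outside the gene table, and 8730 were outside the probe table used here and are unnamed. No probe set was paired with RNS2 there, so the level of RNS2, planned as a check of the labels, was not analysed here.

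The comparison was rns2-2 minus Col-0, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options), two-sided, with Benjamini-Hochberg adjustment over the 22746 probe sets and a threshold of 0.05. No filter on dim probe sets and no replicate block were used. Standard errors are those of the limma fit, and SD is over the 3 arrays of a genotype. Single values outside this fit were compared with a two-sided exact permutation test, which cannot give less than 0.1 with 3 arrays against 3.

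Before the data were examined, 31 gene lists, the designs, the alternatives and the rule for named genes were fixed. Lists were matched by locus, with the brightest probe set of each locus. Of 557 list entries, 104 had a named probe set here. The 5 lists with 5 or more measured loci were tested with camera at a preset correlation of 0.01, with adjustment over those 5 lists. A further 21 lists had 1 to 4 measured loci and were compared gene by gene. The remaining 5 had no measured locus: cytosolic ribosomal proteins, plastid ribosomal proteins, phosphate starvation, salicylic acid and pathogen response, and seed storage. The ribosomal lists rested on words in gene synonyms, since the gene table had no descriptions, and are incomplete. Camera was repeated with an estimated correlation, and fry, a test of whether the genes of a list move one way, was run as an alternative.

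The rule named RNS2 and the RNase T2 family, the 15 largest changes per direction among probe sets past the threshold, and, where fewer than 5 passed in a direction, the 10 with the smallest unadjusted p and non-overlapping groups among probe sets brighter than the median. It also named up to 4 members per list with the smallest unadjusted p, and loci next to RNS2 past the threshold. To keep the text short, after the values were seen, the list members were narrowed to those with an unadjusted p under 0.05, plus the measured members of the RNase, root and clock lists. The 49 others are given only in counts.

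Alternatives fixed beforehand were quantile normalization, median centring, filters at the 25th percentile and the median, an intensity trend or a robust prior, no moderation of the variance, array weights, a replicate block, leaving out probe sets that may bind several transcripts, other thresholds, another choice of probe set per locus, and leaving out each array. The pseudocount alternatives did not apply, because the values were already log2. Alternatives for the arrays of replicate 1, and the expansin list without EXPA4, were added after the data were seen.

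The limma step was tested on 20 simulated data sets of this comparison over 22746 probe sets, with 200 changed probe sets in each. It called 43.4% of 2-fold changes, 84.3% of 4-fold changes and 97.8% of 32-fold changes, and 5.13% of its calls were false. These shares hold for 200 changed probe sets. With fewer, the adjustment is stricter, so they overstate what could be called where 1 probe set passed. AT1G02660, 4.28-fold lower in rns2-2, did not pass in the real data (limma adjusted p = 0.239). In 50 simulations over 13286 loci, camera called a list of 8 loci shifted by 0.70 log2 units in 100% of runs and an unshifted list in 2%. The simulated genes were independent of each other, which real genes are not. Figures were drawn with matplotlib 3.10.9.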

Results

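The data are log2 expression values from 6 Arabidopsis seedling arrays, 3 of the wild type Col-0 and 3 of rns2-2, each from 10-day-old plants raised on agar medium. The mutant is named for RNS2, a ribonuclease of the RNase T2 family that resides in the vacuole and endoplasmic reticulum and acts in the decay of ribosomal RNA. The comparison asked which transcripts differed between the genotypes.

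A single probe set, 245067_at, changed in rns2-2. It was 39.4-fold lower than in Col-0, at 5.11 ± 0.06 log2 units against 10.41 ± 0.18 (SD, n = 3 arrays each; log2 change -5.30, SE 0.12, limma adjusted p = 0.000169). Its rns2-2 level lay below the array medians (6.51 to 6.66) and could not be separated from background, so the fold may be a lower limit. The table used here does not pair this probe set with a gene, so it is given by its identifier. No named gene passed the test, and the next smallest limma adjusted p was 0.239. Of the RNase T2 family, only RNS4 and RNS5 were measured by named probe sets. Their log2 changes were -0.03 (SE 0.31) and -0.13 (SE 0.19), within the spread between arrays, and the level of RNS2 itself was not analysed here.

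The following 20 genes had the smallest unadjusted p per direction with no overlap between genotypes, and none passed the adjusted test (limma adjusted p 0.239 to 0.275). Among those with higher values in rns2-2 was GH9C2, an endoglucanase of the cell wall, at 8.41 ± 0.20 against 6.77 ± 0.15 in Col-0 (SD, n = 3; log2 change 1.64, SE 0.15). The expansins EXPA4 and EXPA15, proteins that loosen cell walls, had log2 changes of 1.63 (SE 0.24) and 1.25 (SE 0.17). The thaumatin-like protein genes AT2G28790, AT4G38660 and ATLP-1 had log2 changes of 1.37, 1.07 and 0.97. AT1G74460, of the GDSL lipase family, stood at 1.10, and CXE18, a carboxylesterase, at 1.07. AT3G19540 and the L-ascorbate oxidase gene AT5G21105 had smaller differences, of 0.66 and 0.59.

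Among the genes with lower values in rns2-2, AT1G02660, a plastid lipase, stood at 7.29 ± 0.37 against 9.38 ± 0.32 in Col-0 (SD, n = 3; log2 change -2.10, SE 0.24). AT1G05575 and AT3G04640 had log2 changes of -2.02 (SE 0.26) and -1.91 (SE 0.26). AT5G51390 stood at -1.65, AT5G66650, of the mitochondrial calcium uniporter family, at -1.63, AT2G28400 at -1.45 and AT3G10020 at -1.42. AT4G29950 had a log2 change of -1.34, the expansin-like gene EXLA1 -1.04 (SE 0.12) and AT1G18270 -0.94.

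**Figure D1:**
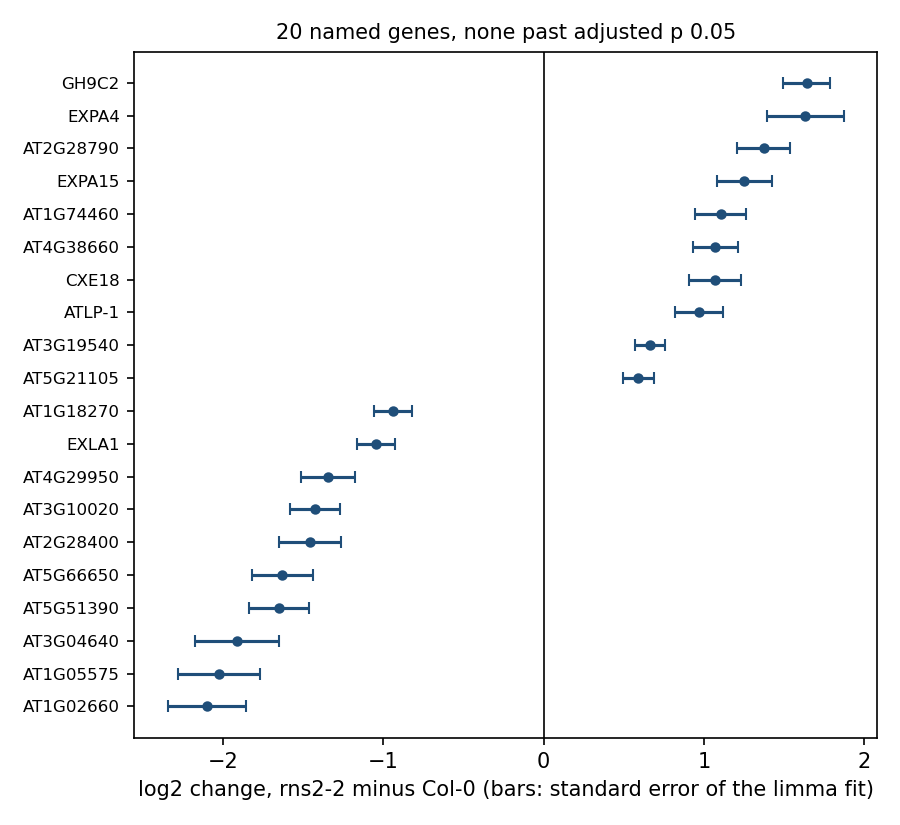
The horizontal axis gives the log2 change, rns2-2 minus Col-0, of the 20 genes named by size of p, with 3 arrays per genotype; points are estimates and bars the standard error of the limma fit. The values run from -2.10 for AT1G02660 to 1.64 for GH9C2, and none passed the adjusted test.

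The list of expansins and xyloglucan endotransglucosylases, proteins that remodel the wall of growing cells, rose in rns2-2 with camera at its preset correlation. Its 8 measured members of 24 had a mean log2 change of 0.66, and 7 of the 8 were above 0 (camera adjusted p = 0.000362). With an estimated correlation the camera adjusted p was 0.221, and with fry it was 0.137. The 95% interval of the mean ran from -0.07 to 1.39. EXPA4, XTH20 and XTH16 had log2 changes of 1.63, 0.85 (SE 0.27) and 0.67 (SE 0.26). EXPA4 was the 1 member past 0.05 adjusted over the list alone, and 0 passed over all probe sets with limma. The list means of the rns2-2 arrays, relative to the Col-0 mean, were 0.98, 0.69 and 0.31, and the highest Col-0 array, replicate 1, stood at 0.35.

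Autophagy genes, which deliver cell material to the vacuole, were lower as a list in rns2-2 with camera at its preset correlation. The mean log2 change of 17 measured members of 32 was -0.31, and 16 of the 17 were below 0 (camera adjusted p = 0.0466). With an estimated correlation the camera adjusted p was 0.577, and with fry it was 0.457. The 95% interval of the mean ran from -0.88 to 0.25. The ubiquitin-like genes ATG8H, ATG8E and ATG8B had log2 changes of -0.97 (SE 0.37), -0.96 (SE 0.32) and -0.77 (SE 0.22), and ATG13B, of the ATG1 kinase complex, -0.45 (SE 0.16). None of the 17 passed 0.05 adjusted over the list alone or over all probe sets with limma. Replicate 1 of rns2-2, an array that stood apart, had the lowest list mean, -0.58, beside 0.03 and -0.39 in the other rns2-2 arrays. Across the 6 arrays, the list mean correlated at 0.632 with the 3' minus 5' difference of control transcripts, a sign of RNA quality (0.477 within genotypes), and at -0.0175 with the RNA controls added before labelling (0.609 within genotypes). The call also ended with median centring (camera adjusted p = 0.0635), with an intensity trend (0.0894) and with the replicate block (0.0761), and without replicate 1 of Col-0 (mean -0.24, camera adjusted p = 0.605), replicate 1 of rns2-2 (mean -0.18, camera adjusted p = 0.478) or replicate 3 of rns2-2 (mean -0.28, camera adjusted p = 0.129). With replicates 2 and 3 only, the mean was -0.10 and camera pointed the other way (camera adjusted p = 0.978).

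**Figure D2:**
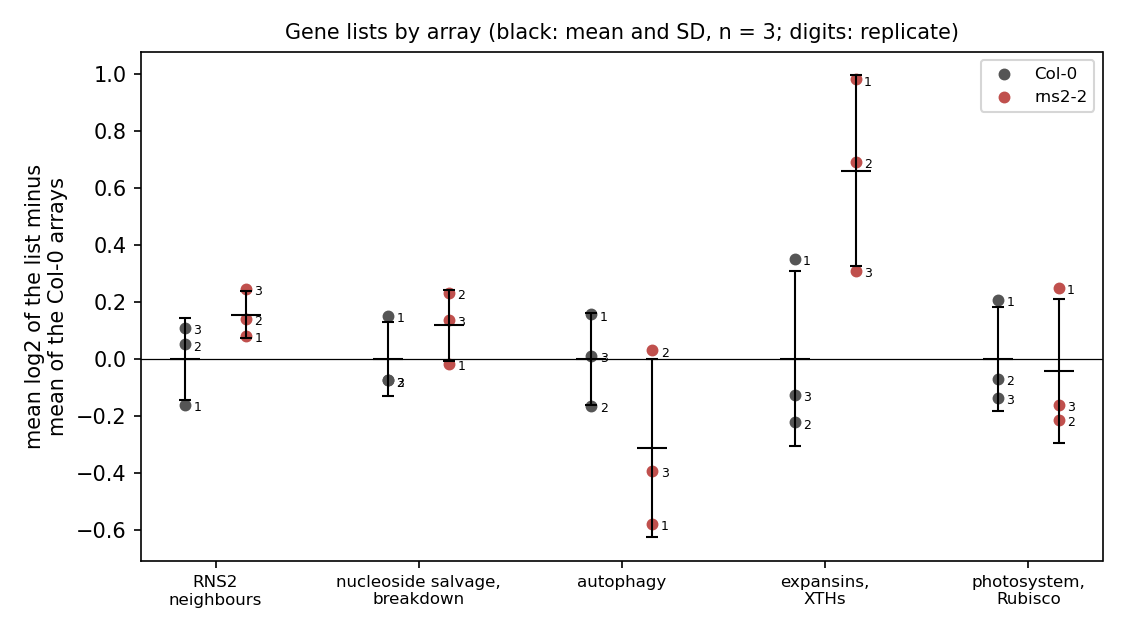
The vertical axis gives the mean log2 value of each tested gene list per array, relative to the mean of the Col-0 arrays; points are arrays, the digit is the replicate and black bars are the mean and SD of 3 arrays. Expansins and xyloglucan endotransglucosylases (XTHs) stand at 0.98, 0.69 and 0.31 in rns2-2, and the autophagy list at -0.58, 0.03 and -0.39.

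The other tested lists did not pass. The 9 measured loci next to RNS2 had a mean log2 change of 0.15 but a median of -0.05 (camera adjusted p = 0.535), and EXPA4 alone among them passed 0.05 adjusted over the list alone. The 6 genes of nucleoside salvage and nucleotide breakdown had a mean of 0.12 (camera adjusted p = 0.535), with UPP, a uracil phosphoribosyltransferase, at 0.35 (SE 0.11); their array mean correlated with the labelling controls at 0.896 (0.868 within genotypes). The 8 photosystem and Rubisco subunits, which stand for shoot material, had a mean of -0.04 (camera adjusted p = 0.637).

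Lists with 1 to 4 measured members were compared gene by gene, and 0 of their members passed over all probe sets with limma. All 3 measured carbon starvation markers of 14 were lower and passed 0.05 adjusted over the list alone. MCCA and IVD, enzymes of leucine breakdown, had log2 changes of -1.83 (SE 0.30) and -1.87 (SE 0.31), and SEN5 -0.54 (SE 0.21). For SEN5 the genotypes overlapped, and its adjusted p over the list equalled its unadjusted limma p of 0.0436. Adjusted over the list alone, ZAT10, a zinc finger regulator induced by stress, passed in the list of reactive oxygen responses, where 2 genes were measured, with -2.47 (SE 0.65). WRKY53, a regulator of leaf senescence, passed in the list of 3 measured senescence genes, with -1.18 (SE 0.23), and WRKY6 beside it stood at -0.95 (SE 0.37) without passing.

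In the remaining small lists, 0 members passed 0.05 adjusted over the list alone. In the abscisic acid, cold and drought list, the cold-induced COR15A stood at 9.97 ± 2.13 in rns2-2 and 7.10 ± 1.09 in Col-0 (SD, n = 3; log2 change 2.87, SE 1.12), with overlap between the genotypes and a range from 7.66 to 11.86 among the rns2-2 arrays. In the pentose phosphate pathway PGD3, a 6-phosphogluconate dehydrogenase, stood at 0.82 (SE 0.29). In starch and sucrose metabolism the log2 change was 0.47 (SE 0.17) for APL3, a subunit of ADP-glucose pyrophosphorylase. It was -0.27 (SE 0.11) for the amylase AMY1. Both were dim, with means in Col-0 and rns2-2 of 4.54 and 5.01 for APL3 and 4.42 and 4.15 for AMY1. These levels lay below the array medians and could not be separated from background. The chaperone gene CRT2 of the unfolded protein response stood at 0.42 (SE 0.17), and the replication gene MCM7 of the cell cycle list at 0.53 (SE 0.20). The root markers PYK10, EXPA18 and EXPA7 had log2 changes of 0.20 (SE 0.13), 0.25 (SE 0.28) and 0.11 (SE 0.45), and GI, the 1 measured gene of the clock list, -0.64 (SE 0.50). No measured member passed for de novo nucleotide synthesis (3 genes), ribosome biogenesis (3), TOR and SnRK1 signalling (2), cellulose synthases (1) or vacuolar proteins (4). The same was true of jasmonate and wounding (2), auxin and brassinosteroid response (3), the anthocyanin pathway (3), heat shock (1) and unlinked housekeeping genes (4).

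Without adjustment, 2425 of 22746 probe sets had a limma p under 0.05, where 1137 would arise by chance if all arrays were independent. Of these 2425, 1217 were higher and 1208 lower in rns2-2. With a change of 2-fold besides, 93 were higher and 235 lower. The genotypes did not overlap at 4203 probe sets, or 18.5%, where chance gives 10% if all arrays are independent. These chance levels may not hold if replicates 2 and 3 of a genotype were not independent, so no excess over chance is shown. Other splits of the arrays, 3 against 3, gave from 294 to 3397 probe sets at an unadjusted limma p under 0.05. Replicates 2 and 3 were close to each other in both genotypes, and replicate 1 stood apart in both. The log2 difference between replicates 2 and 3 had an SD across probe sets of 0.20 in Col-0 and 0.31 in rns2-2. Between replicate 1 and the others of its genotype this SD was 0.58 and 0.58 in Col-0 and 0.59 and 0.61 in rns2-2. Replicate 1 of Col-0 was closer to each rns2-2 array (SD 0.54, 0.51 and 0.56) than to the other Col-0 arrays. Replicate 1 of rns2-2 stood about as far from replicates 2 and 3 of Col-0 (0.58 and 0.58) as from those of rns2-2. By probe sets 2-fold apart it was no closer to these Col-0 arrays: 1726 and 1634, against 1613 and 1775 within rns2-2. Its SD from replicate 1 of Col-0 was 0.54. The groups are used as the labels give them. The labels call all 3 independent; if replicates 2 and 3 shared material, the p-values measured partly technical spread. The count of 1 probe set rested on replicate 1: it was 333 without replicate 1 of Col-0 and 32 without replicate 1 of rns2-2, each time with 245067_at among them. With replicates 2 and 3 averaged into 1 sample per genotype, 0 probe sets passed with limma (895 at an unadjusted p under 0.05), and 245067_at kept its log2 change of -5.29 with an adjusted p of 0.1001.

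**Figure D3:**
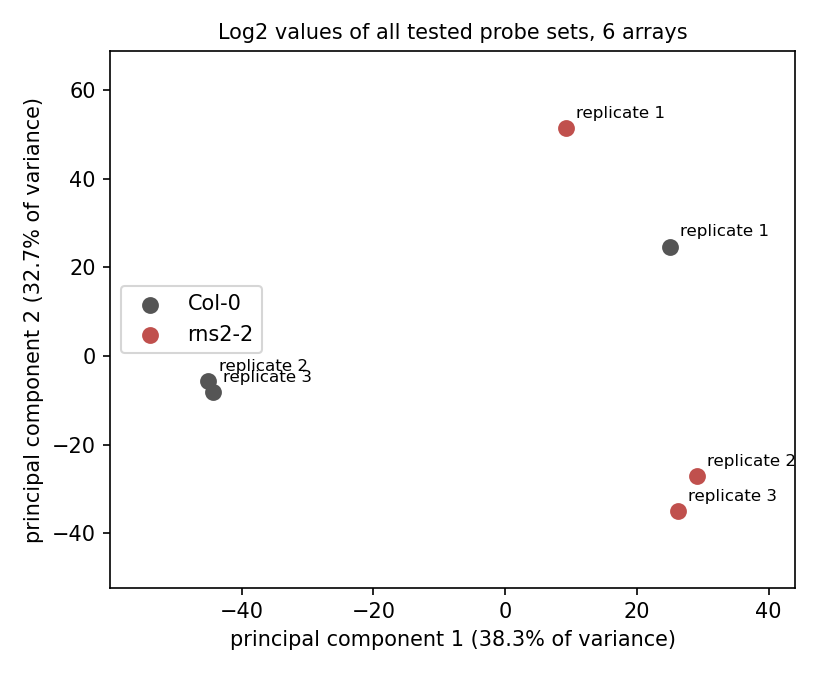
The axes are the first principal components of the log2 values of all tested probe sets, holding 38.3% and 32.7% of the variance; each point is an array, coloured by genotype. Replicates 2 and 3 of each genotype lie next to each other, while replicate 1 of Col-0 and replicate 1 of rns2-2 lie on the positive side of the second axis, at 24.6 and 51.4. On the first axis replicate 1 of Col-0 stands at 24.9, among the rns2-2 arrays (9.23 to 29.1).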

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

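The alternatives with replicates 2 and 3 only, with these averaged, with a 2-level block of replicate 1 and without EXPA4 were chosen after the data were seen; the others were fixed before. The count of changed probe sets stayed at 1 in 15 alternatives. It was 435 with array weights (209 higher, 226 lower), 328 at an unadjusted p under 0.05 with a 2-fold change, 3262 with replicates 2 and 3 only (1660 higher, 1602 lower), 0 with replicates 2 and 3 averaged, and 1 to 333 when single arrays were left out, the highest without replicate 1 of Col-0; without replicate 1 of rns2-2 it was 32. The 333 were all among the 3262 and 154 of them among the 435, but only 4 of them among the 32. The probe set 245067_at kept its direction throughout and lost its call only with replicates 2 and 3 averaged (log2 change -5.29, adjusted p = 0.1001), a fit with fewer samples. No general pairing of the arrays by replicate number was seen: the deviations of same-numbered arrays correlated at 0.06, -0.06 and 0.14 across probe sets. These values are not independent, since the deviations within a genotype sum to 0, and they do not exclude shifts shared at some genes. With the replicate block, 1 probe set passed and 1 list was called. The 20 genes named by p kept their direction in all 380 alternative values and passed in 58, with adjusted p from 7.12e-05 to 0.935. Of the tested lists, 2 were called; 1 was called with median centring, above the median, with an intensity trend, with the replicate block and with replicates 2 and 3 only, 0 with an estimated correlation and 0 with fry, and 1 to 2 without single arrays. Expansins and xyloglucan endotransglucosylases kept a mean of 0.66 but no call with an estimated correlation (adjusted p = 0.221) and fry (0.137); above the median fewer than 5 members remained and no test was made. The autophagy list lost its call with median centring (mean -0.37, adjusted p = 0.0635), with an intensity trend, the replicate block, an estimated correlation and fry (mean -0.31 in each, adjusted p = 0.0894, 0.0761, 0.577 and 0.457). Its mean ran from -0.49 to -0.18 without single arrays, and with replicates 2 and 3 only the mean was -0.10 while camera pointed up (adjusted p = 0.978). Values near 0 changed sign: the photosystem list (-0.19 to 0.061 without single arrays), RNS4 (-0.28 to 0.24 without single arrays, 0.18 with replicates 2 and 3 averaged), RNS5 (0.000895 with these averaged), EXPA18 (-0.034 with replicates 2 and 3 only) and EXPA7 (-0.35 to 0.49 without single arrays, -0.17 with array weights, -0.54 with replicates 2 and 3 only). Among 916 alternative values of the 49 list members not named, 57 changed sign and 0 of those passed, while 15 passed with their sign kept, 4 without replicate 1 of Col-0 and 11 with replicates 2 and 3 only. Apart from fewer samples or genes, the cause was not tested. The robust prior was not run for the lists, and no alternative was run for RNS2. Dim probe sets could not be set against background, since no detection calls were used.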

Other observations

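The gene groups below, and the tests of them, were chosen after the data were seen, as were all other tests in this part except those of the time of day, of RNA integrity and of other splits of the arrays. Plastid-encoded genes had the smallest camera p of 44 groups at the preset correlation: their 69 measured loci had a mean log2 change of -0.65 in rns2-2, with 60 below 0 and 9 above (camera adjusted p = 2.27e-07). With an estimated correlation the camera adjusted p was 0.704, and other groups then had smaller p. The plastid means of the arrays, relative to the Col-0 mean, were 0.40, -0.24 and -0.16 in Col-0 and -0.71, -0.92 and -0.32 in rns2-2, so the genotypes did not overlap. A sign of RNA quality moved with them: the 3' minus 5' log2 difference of the actin, GAPDH and ubiquitin controls was 2.43, 1.19 and 1.53 in Col-0 and 0.79, 1.17 and 1.65 in rns2-2, highest in the array with the highest plastid mean and lowest in the 2 arrays with the lowest. The correlation of the plastid mean with it was 0.866 over the 6 arrays and 0.875 within genotypes. The RNA controls added before labelling stood at 5.66 ± 0.28 in Col-0 and 6.14 ± 0.42 in rns2-2 (log2, SD, n = 3; exact permutation p = 0.2), with a correlation with the plastid mean of -0.184 over the 6 arrays and 0.627 within genotypes. Examples, picked after their values were seen, are rpl20, of the plastid ribosome, at -2.16 (SE 0.53), rpoC1, of the plastid RNA polymerase, at -1.77 (SE 0.37), petG at -1.63 (SE 0.31) and the photosystem II gene psbD at -1.58 (SE 0.40). The mean stayed below 0 and past the adjusted threshold with quantile normalization, with median centring and without each array, in 8 of 8 settings (-0.81 to -0.45). The nuclear-encoded photosystem and Rubisco list, in contrast, had a mean of -0.04. The difference between these groups was not tested. How well amplification from 3' ends captures plastid transcripts was not tested either, so the plastid mean may not give their level.

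The other groups are loci that share a symbol prefix, which can miss members of a gene family or add unrelated genes. Of the 44 groups, 8 passed with the preset correlation and 0 with an estimated one. The ATG prefix was among the 8, but it holds only 8 of the 17 measured autophagy genes and is not described apart from that list. Beta-tubulin genes (TUB) had a mean log2 change of 0.45 with 5 of 5 above 0, led by TUB1 at 1.01 (SE 0.17) and TUB7 at 0.58 (SE 0.13). The means were also above 0, with members on both sides, for the calmodulin-binding IQD family (mean 0.22, 12 above 0 and 3 below), the TRM genes named for the TON1 recruiting motif (0.21, 10 and 4, leaving out TRM82, a tRNA modification gene that shares the prefix; camera adjusted p = 0.0179), the ubiquitin-specific proteases UBP (0.18, 10 and 2) and the alpha-expansins EXPA (0.50, 8 and 2). Calmodulin-like genes with the prefix CML were below 0 in 7 of 7 loci, with a mean of -0.63 and a median of -0.31, CML38 at -2.29 (SE 0.53) and CML37 at -0.42 (SE 0.10). Without CML38 the mean of the other 6 was -0.35 (camera adjusted p = 0.0748). Without the 1 member that moved furthest, the threshold was also missed by TUB (mean 0.30 without TUB1, camera adjusted p = 0.0926), EXPA (0.38 without EXPA4, 0.0547) and UBP (0.15 without UBP25, 0.0622). The sign of the mean of all 8 groups stayed the same under both scalings and without each array, but the 7 smaller ones each missed the threshold in some of these settings. Array means of the genotypes overlapped for TUB, TRM and IQD. Without replicate 2 of Col-0 the mean was 0.11 for TRM and 0.14 for IQD. Correlations of the array means with the 3' minus 5' difference, over all arrays and then within genotypes, were 0.388 and 0.969 for TRM, 0.228 and 0.942 for IQD, -0.242 and 0.423 for UBP, -0.401 and -0.0920 for TUB, -0.266 and 0.332 for EXPA, and 0.158 and -0.766 for CML. With the labelling controls they were 0.902 and 0.845 for TRM, 0.884 and 0.796 for IQD, 0.741 and 0.492 for UBP, 0.629 and 0.340 for TUB, 0.563 and 0.0618 for EXPA, and -0.751 and -0.533 for CML. The 25S ribosomal RNA control probe set stood at 12.70 ± 0.25 in Col-0 and 12.29 ± 0.47 in rns2-2 (SD, n = 3; exact permutation p = 0.3). The 5S control stood at 3.90 ± 0.05 and 3.75 ± 0.07 (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give). These 5S values lay near the lowest values of the arrays (3.21 to 3.48) and could not be separated from background.

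With 6 arrays there are 10 splits of 3 against 3, too few for a share under 0.05. The real split called 1 probe set, and the highest of the others called 2, so 2 of the 10 splits called as many. The split that put replicate 1 of Col-0 with replicates 2 and 3 of rns2-2 gave those 2, and 3397 probe sets at an unadjusted limma p under 0.05 against 2425 for the real one. It differs from the real split only in the replicate 1 arrays, so it keeps the genotype difference of replicates 2 and 3. For the gene lists, the real split called 2 and the highest other 2, which 2 of the 10 splits reached. The expansin list alone had a camera p of 7.25e-05 in the real split and 1.24e-05 in the split that put replicate 1 of Col-0 with replicates 1 and 2 of rns2-2.

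Replicate 1 of each genotype stood apart from replicates 2 and 3. The 3' minus 5' difference of the controls was highest in replicate 1 of Col-0 (2.43) and lowest in replicate 1 of rns2-2 (0.79). The other arrays lay from 1.17 to 1.65. Whether RNA quality set the replicate 1 arrays apart was not tested and stays open. A batch that shifted both replicate 1 arrays the same way is argued against as the whole cause. The correlation across probe sets between the deviations of replicate 1 in Col-0 and in rns2-2 was only 0.0586. A batch that acted differently on each of these arrays could also leave a low correlation, so it stays open. An exchange of the replicate 1 arrays between genotypes is argued against as the whole cause: they would still stand apart. Their SDs to replicates 2 and 3 of the other genotype were 0.51 to 0.58, while those replicates differed by 0.20 and 0.31. An exchange with another cause, or a batch crossing the genotypes, stays open. With these arrays exchanged, 71 probe sets had a gap over 1 log2 unit between groups, against 25 as labelled. The widest gap was 5.11 as labelled, for 245067_at, and 3.11 exchanged, for another probe set. Replicate 1 of 245067_at followed the labels, at 10.34 in Col-0 and 5.06 in rns2-2, which for this probe set argues against an exchange. It was picked with all arrays, but also had the smallest limma adjusted p with replicates 2 and 3 only (1.82e-05). Another time of day at harvest may account for part of the separation of replicate 1 and stays open. In its test, 7 clock genes gave a mean product of deviations at percentile 98.3 of 10000 random lists, past the level set beforehand. A check added afterwards gave only percentile 80.9 without CDF5, which held 87.2% of the sum. Of the genes seen before this test, replicate 1 minus the others was -6.28 in Col-0 and -5.95 in rns2-2 for the clock-regulated COR27. It was -5.85 and -4.54 for AT4G33980, -5.33 and -5.60 for AT1G56300, and -4.68 and -4.39 for AT1G07050. GI had -1.15 and -0.46, but HYH -0.11 and 4.44. Of the 7 tested genes, CDF5 had 1.935 and 2.154, CCL -0.22 and -3.70 and TIC 0.22 and -0.69. LIP1 and FIO1 had small values of the same sign in both genotypes, while AT5G52660 and AT4G01280 had opposite signs. Of 520 probe sets 2-fold apart in both genotypes, 63.1% went the same way.

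ZAT10, WRKY53 and CML38, genes known to respond rapidly to stress, had log2 changes of -2.47, -1.18 and -2.29, and none passed over all probe sets with limma. Whether such genes were lower as a class stays open: CML23, CML37, CML39, PUB22, PUB23 and PUB24 had a mean log2 change of -0.22 (fry adjusted p = 0.0534 over 2 added list tests), short of the -0.5 that was set, and CML23 and CML37 had already been seen in the CML group (the PUB genes alone had -0.17). A list of 19 hypoxia-response genes, written after AT3G10020 and CML38 were seen and leaving them out, did not stand apart (mean -0.18, camera adjusted p = 0.798 over the same 2 tests). RNA integrity also stays open, since the 3' minus 5' difference of the controls differed by a mean of -0.51 (1.21 ± 0.43 in rns2-2, 1.72 ± 0.64 in Col-0, SD, n = 3; exact permutation p = 0.4), and by -0.15 without replicate 1 of Col-0. An effect of the genotype stays open beside these and was not tested on its own.

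The expansin and xyloglucan endotransglucosylase list was higher in rns2-2 with camera at its preset correlation. Whether EXPA4, which neighbours RNS2, was the only source stays open: without it 6 of 7 members were above 0, with a mean of 0.52 and a camera p of 0.00172, but the 95% interval ran from -0.30 to 1.35, the adjusted p with an estimated correlation was 0.504, and 3 of the 10 splits of the arrays, the real one included, gave a camera p as small. A different share of root or shoot material could not be excluded: the 3 root markers had a mean of 0.18 with a 95% interval from -0.71 to 1.07, which holds the 0.66 of the expansin list, and the photosystem list had -0.04 (-0.55 to 0.46). An effect of the mutation on growing tissue is a hypothesis that was not tested and stays open beside it. The call was lost at an estimated correlation (camera adjusted p = 0.221).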
